A study of Mus musculus with 20 samples.

How the data were processed

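Bulk RNA was measured in 20 libraries of mouse organoids, which are epithelial cultures grown in a gel as small hollow or solid bodies. The cultures come from the L2-IL-1B mouse, a model in which interleukin 1 beta is overexpressed in the esophagus and which develops a Barrett-like epithelium at the junction of esophagus and stomach. The labels divide the libraries by genotype into L2-L (7 libraries), L2-LP (5), L2-LK (1) and L2-LKP (7), call all of them intestinal metaplasia and give no treatment. The labels do not spell out what the letters stand for, and the series title names TRP53 and KRAS. All cultures grew in medium conditioned by Wnt-producing cells, with EGF and a ROCK inhibitor. The labels also give 3 batches. RNA of batches 1 and 2 was isolated with one column kit and the libraries were made by a sequencing company. RNA of batch 3 was isolated with another kit, the libraries were made in a university laboratory, and sequencing was spread over 4 runs that were part of a larger project with many samples.

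The deposited table holds raw counts per gene symbol, whole numbers with no normalization, for 23348 genes, of which 3015 had no count in any library. Its genome build is GRCm38, per the submitters' processing notes, which also name DESeq2. The aligner, the counting tool, the annotation and the use of strand are not given in the sources used here, nor whether the counts of batch 3 are reads or molecules. All 20 columns of counts were matched to samples by name, and no count stood for reads outside genes. Of the symbols, 92.8% were found in the GENCODE annotation for GRCm38, release M21, from which gene positions were taken. Without stated strand use, counts of overlapping genes on opposite strands cannot be told apart.

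Depth differed strongly between batches. Libraries of batches 1 and 2 held 34259284 to 40782908 counts over 15336 to 16785 genes, and libraries of batch 3 held 225568 to 301703 counts over 10876 to 11921 genes. The median library of batches 1 and 2 was thus 147 times deeper than that of batch 3. A floor of 3 counts stands for 0.0736 to 0.0876 CPM (counts of a gene scaled to a common library total) in batches 1 and 2 and for 9.94 to 13.3 CPM in batch 3. Intervals and floors cover counting error only. All pairs of replicates within a genotype and batch differed by more than sampling noise, with chi-square values per degree of freedom of 83.0 to 416 in batches 1 and 2 and 2.70 to 6.09 in batch 3, and each library was counted as 1 sample. Nothing in the labels says that replicates are separate cultures or animals, and replicate numbers recur across batches within a genotype. The p-values therefore measure only the spread between these samples, which may be technical.

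The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The 19 libraries of L2-L, L2-LP and L2-LKP were fitted together with edgeR 4.0.16 in R 4.3.3, with genotype and batch as terms and TMM normalization. Genes were kept by filterByExpr with its minimum count of 10, which left 14396. The quasi-likelihood F test (prior degrees of freedom 5.14) gave each gene's log2 fold change, with a standard error (SE) taken from the fold change and the F value, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Group levels are given as CPM with the standard deviation (SD) over libraries, scaled by the TMM factors for the comparisons and by the total count where single libraries are described. Folds within a batch come from the same fit on the libraries of that batch alone, over the same genes. Where every library of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio of pooled counts is given with its exact interval of 95%.

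The 20 gene lists hold 391 genes in all and cover p53 targets, ERK pathway output, RAS pathway components, cell cycle, intestinal differentiation, gastric pit cells, gastric gland cells, stem cells and WNT targets, fetal and regenerative epithelium, inflammatory and NF-kB genes, interferon-stimulated genes, antigen presentation, EMT and invasion, glycolysis, cholesterol synthesis, stress and handling response, squamous epithelium, enteroendocrine and tuft cells, fibroblasts, and immune and endothelial cells. Tigar, Mucl3, Muc6, Cblif, Atp4b, Ccn2, Ccn1, Aldoa, Ddit3, Il25 and Adgre1 were not analysed here. In the comparisons between genotypes, shares of a list refer to its tested genes, which filterByExpr kept, and not to all its members. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01 and with Benjamini-Hochberg adjustment over 60 tests. This two-sided test asks whether a list's genes were shifted up or down relative to other genes, so moves in both directions can cancel. The tests were repeated with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. The named genes are, per comparison, the 8 higher and 8 lower genes with the largest fold among called genes with at least 1 CPM on average and one sign within all batches, up to 4 members of each list with the smallest adjusted p, and 12 genes fixed by name. Only some of these appear in the text.

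The single L2-LK library entered no test between genotypes. Its log2 CPM, with a prior count of 2, were set against the mean of the L2-L libraries of batch 3 for 8070 genes with a mean of at least 3 counts in that batch, beside the L2-LP and L2-LKP libraries of batch 3. A list's median was placed among 10000 random lists of the same size, matched on mean expression. This ranks genes within a library and says nothing about spread between libraries. Alternatives tried were DESeq2 1.42.0, RLE normalization, other filters, no batch term, the replicate number as a block, a random effect for genotype and replicate number, other sets of libraries and the omission of each library.

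The fit was checked on simulated counts in which 67, 67 and 66 of the 14396 genes changed by 1.5, 2 and 4 times, drawn from the real means and library sizes. For L2-LP against L2-L, 2.99%, 22.4% and 84.8% of these 3 sets were called. For L2-LKP against L2-L the shares were 11.9%, 40.3% and 86.4%, and for L2-LKP against L2-LP they were 5.97%, 28.4% and 77.3%. Among the called genes, 5.95%, 0.926% and 1.25% were unchanged in the simulation. The 1 list that was shifted was called in each of the 3 comparisons and no other list was. Each gene was drawn independently of the others, so this check does not cover lists whose genes move together.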

Results

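RNA was sequenced from 20 libraries of mouse organoids from the L2-IL-1B mouse, spread over 4 genotypes and 3 batches. Batch 1 held 3 L2-L and 2 L2-LKP libraries, and batch 2 held 2 libraries each of L2-L, L2-LP and L2-LKP. Batch 3 held 2 L2-L libraries, 3 each of L2-LP and L2-LKP, and the only L2-LK library. Libraries of batches 1 and 2 held 34259284 to 40782908 counts each and those of batch 3 held 225568 to 301703. In the edgeR quasi-likelihood fit with Benjamini-Hochberg adjustment, 8099 of 14396 genes differed between batches 3 and 2 and 310 between batches 2 and 1, so within-batch values are given beside each comparison.

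Trp53 and Kras, the genes in the series title, were measured first. Trp53, on chromosome 11 at 69580359 to 69591873 (GRCm38, plus strand, protein-coding, no overlapping gene), encodes the p53 transcription factor. In batches 1 and 2 its level was 175 CPM ± 28.3 (SD, n = 5) in L2-L and 2.70 CPM ± 1.77 (n = 4) in L2-LKP. The 2 L2-LP libraries of batch 2 held 43.0 CPM (replicate 1) and 2.07 CPM (replicate 2). In batch 3, Trp53 stood at 138 CPM ± 35.9 (n = 2) in L2-L, 35.7 CPM ± 11.3 (n = 3) in L2-LP and 56.3 CPM ± 11.4 (n = 3) in L2-LKP. The L2-LK library held 44 counts, or 146 CPM (exact Poisson interval 106 to 196), inside the range of L2-L at 113 to 164 CPM. Trp53 thus fell in L2-LP (log2 fold change -3.04, SE 0.80, adjusted p = 0.0086) and in L2-LKP (-5.04, SE 0.84, adjusted p = 0.00012) by the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment. The call in L2-LP was lost without batch 3 (adjusted p = 0.064) and without a batch term (0.080). Which part of the gene the counts cover is not given in the sources used here, so counts from outside a deleted part would remain.

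Kras, on chromosome 6 at 145216699 to 145250239 (minus strand, protein-coding, overlapping Etfrf1), encodes a small GTPase upstream of the ERK kinases. In batches 1 and 2 it stood at 62.5 CPM ± 30.4 (n = 5) in L2-L, where 1 library of batch 1 held 117 CPM and the other 4 held 46.2 to 52.8 CPM. L2-LP held 137 CPM ± 27.8 (n = 2) and L2-LKP 117 CPM ± 15.1 (n = 4). Batch 3 gave 84.9 CPM ± 14.95 (n = 2) in L2-L, 121 CPM ± 39.9 (n = 3) in L2-LP, 160 CPM ± 37.8 (n = 3) in L2-LKP and 146 CPM in L2-LK. The rise in L2-LKP passed the edgeR test (log2 fold change 0.84, SE 0.22, Benjamini-Hochberg adjusted p = 0.0062), and the difference in L2-LP did not (0.73, SE 0.27, adjusted p = 0.051). Without batch 2 the call in L2-LKP was lost (adjusted p = 0.079). Gene totals do not show an activating change in the protein.

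**Figure D1:**
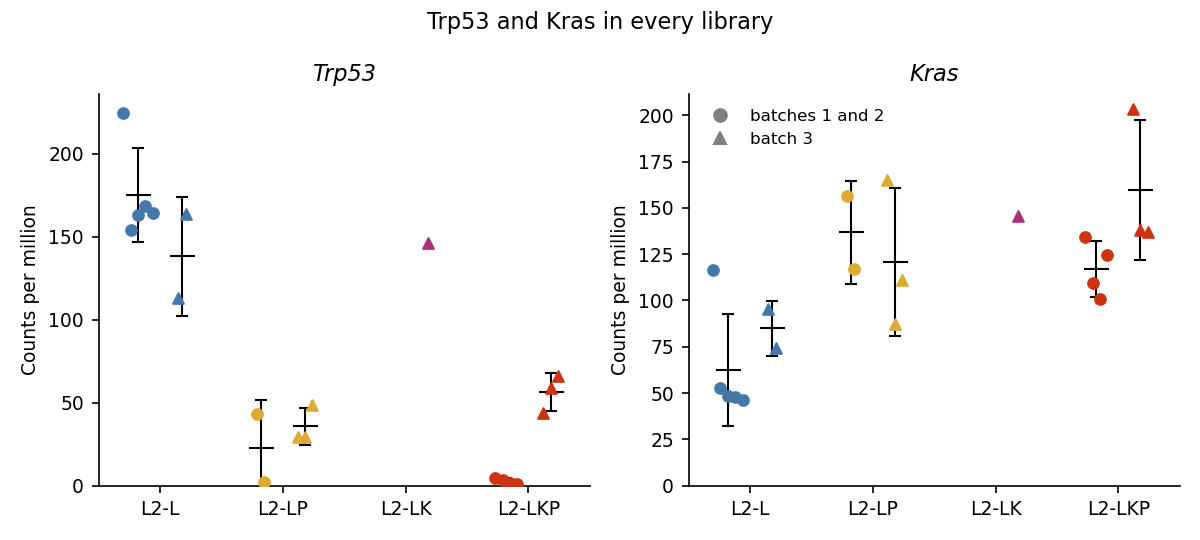
Trp53 and Kras in all 20 libraries in CPM, with circles for batches 1 and 2, triangles for batch 3, and black bars for the mean and SD where a group has more than 1 library. Trp53 in L2-LKP sits between 1.05 and 4.69 CPM in batches 1 and 2 and between 43.8 and 66.3 CPM in batch 3.

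The comparison of L2-LP with L2-L asked how the transcriptome differed between a genotype with low Trp53 counts and L2-L. The 7 L2-L libraries expressed genes of basal squamous cells, such as Krt15 and Trp63, that the other 13 libraries nearly lacked. Krt15, a keratin of basal squamous cells on chromosome 11 at 100131758 to 100135928, ranged from 398 to 2291 CPM in L2-L and from 0.204 to 13.3 CPM elsewhere. Trp63 on chromosome 16 at 25683763 to 25892102, the transcription factor that maintains squamous basal cells, ranged from 59.5 to 484 CPM against 0 to 1.38 CPM. Vil1 on chromosome 1 at 74409376 to 74435559 encodes villin, which bundles actin in the brush border of columnar cells, and showed the opposite picture with 0 to 4.34 CPM in L2-L and 7.97 to 290 CPM elsewhere. Tff2 on chromosome 17 at 31141049 to 31144282, a secreted peptide of gastric mucous cells, ranged from 1.19 to 69.5 CPM in L2-L and from 51.8 to 3220 CPM elsewhere.

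**Figure D2:**
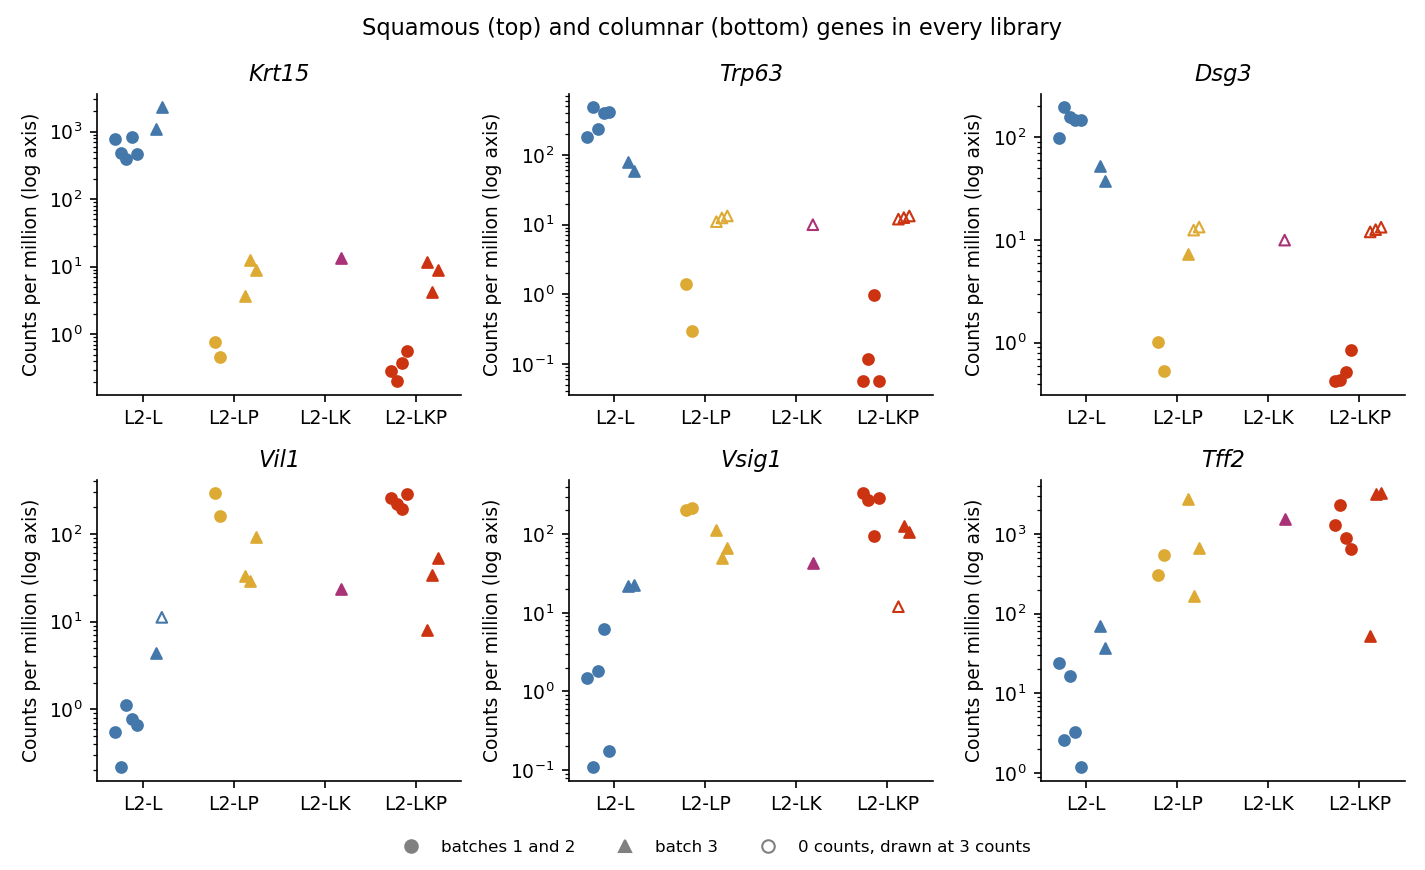
Krt15, Trp63 and Dsg3 (top) and Vil1, Vsig1 and Tff2 (bottom) in all 20 libraries in CPM on log axes, with circles for batches 1 and 2, triangles for batch 3 and open symbols for libraries with 0 counts, drawn at 3 counts. Krt15 separates the 7 L2-L libraries (398 CPM or more) from the other 13 (13.3 CPM or less).

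Of the 15 tested genes on the squamous list, 12 fell in L2-LP and none rose, with 12 lower and 1 higher adjusted over the list alone. The 3 genes not called, named after their values were seen, were Krt4, Ivl and Sprr1a, with log2 fold changes of 0.59, 0.21 and 1.11. Krt15 fell by 9.84 on the log2 scale (SE 0.60, adjusted p = 4.2e-09), from 621 CPM ± 216 (n = 5) in L2-L to 0.547 CPM ± 0.185 (n = 2) in batches 1 and 2. The desmosomal cadherin Dsg3 fell by 7.96 (SE 0.51) and Trp63 by 9.60 (SE 0.79). The list's median log2 fold change was -7.96, with -8.28 within batch 2 and -3.96 within batch 3, and camera gave an adjusted p of 2.5e-12 (adjusted p = 0.00086 with an estimated correlation). Outside the list, the squamous keratin Krt17 had 3 counts in L2-LP against 209975 in L2-L, a ratio of 28330 (counting interval 9694 to 137378), and the calmodulin-like gene Calml3 had none and was at least 1713-fold lower.

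Genes of gastric and intestinal columnar cells rose in L2-LP. On the gastric pit list, which covers the mucous cells of the stomach surface, 10 of 11 tested genes rose and 1 fell, with the same counts adjusted over the list alone. Muc1, a membrane mucin, rose from 238 CPM ± 162 (n = 5) to 990 CPM ± 54.1 (n = 2) in batches 1 and 2 (log2 fold change 2.38, SE 0.35). Anxa10 rose by 4.93 (SE 0.88) and Vsig1, an adhesion protein of gastric epithelium, by 5.98 (SE 1.01). The gene that fell was Psca (log2 fold change -1.76), named after its value was seen. The list's median was 5.98, or 5.22 with the gene lacking counts in L2-L at its bound, with 7.02 within batch 2 and 3.22 within batch 3 (camera adjusted p = 1.7e-05; adjusted p = 0.24 with an estimated correlation).

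On the gastric gland list 5 of 6 tested genes rose, with the same count adjusted over the list alone (median 3.58, 4.08 and 1.18 within batches 2 and 3, camera adjusted p = 0.0020, adjusted p = 0.093 with an estimated correlation). Pgc, which encodes the digestive proenzyme pepsinogen C, had no count in L2-L and was at least 2716-fold higher. Of the 22 genes on the intestinal list only 14 had enough counts to be tested. Of these 14, 7 rose and none fell, with 9 higher adjusted over the list alone (median 2.68, 2.48 and 0.79 within batches 2 and 3, camera adjusted p = 0.013, adjusted p = 0.34 with an estimated correlation). Vil1 rose by 8.39 on the log2 scale (SE 0.50, adjusted p = 4.2e-09). Cdx2, an intestinal master transcription factor on chromosome 5 at 147300805 to 147307270, had 915 counts against 2, a ratio of 1130 over the pooled batches (counting interval 312 to 9347). Both counts in L2-L came from batch 3, where the means of 3.93 CPM in L2-L and 9.21 CPM in L2-LP lay below the floor of 3 counts and the log2 fold change was 1.00.

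The p53 target list fell in L2-LP. Of its 26 tested genes 11 fell and 1 rose, with the same counts adjusted over the list alone. Phlda3, an inhibitor of AKT signalling on chromosome 1 at 135766119 to 135769136, fell by 3.20 on the log2 scale (SE 0.28, adjusted p = 2.3e-07), from 310 CPM ± 38.9 (n = 5) to 29.2 CPM ± 16.3 (n = 2) in batches 1 and 2. Perp, a p53 target that is also a desmosomal protein of stratified epithelium, fell by 2.75 (SE 0.21), Ccng1 by 1.32 (SE 0.26) and the cell cycle inhibitor Cdkn1a by 1.52 (SE 0.43). Mdm2, the ubiquitin ligase that degrades p53, did not pass the test (log2 fold change -0.21, SE 0.20, adjusted p = 0.47). The gene that rose was Tnfrsf10b (0.76), named after its value was seen. The list's median was -0.78, with -0.67 within batch 2 and -0.87 within batch 3 (camera adjusted p = 5.0e-05, adjusted p = 0.025 with an estimated correlation). Without batch 3, 5 members fell and none rose. Cdkn2a, the locus of the cell cycle inhibitors p16 and p19ARF, rose by 1.48 (SE 0.35, adjusted p = 0.0043), a call lost without batch 3 (adjusted p = 0.17), as were those of Ccng1 and Cdkn1a (adjusted p = 0.099 and 0.15). Cdkn1a also lost its call without batch 2 (log2 fold change -1.66, adjusted p = 0.087) and without a batch term (-1.21, 0.29).

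ERK pathway output showed no common direction in L2-LP. Of its 25 genes 3 rose and 4 fell, with the same counts adjusted over the list alone (median 0.04, -0.07 and 0.20 within batches 2 and 3, camera adjusted p = 0.97). Spred1, an inhibitor of the pathway, fell by 0.91 (SE 0.20) and the growth factor Ereg fell by 2.32 (SE 0.53). Without batch 2, which leaves batch 3 as the only one with both genotypes, both lost their calls, with log2 fold changes of -0.55 for Spred1 (adjusted p = 0.48) and -0.88 for Ereg (0.70). Spred1 also lost its call without a batch term (-1.31, adjusted p = 0.12). Dusp5 and Myc were among the higher genes. Their calls were lost without batch 2 too, with log2 fold changes of 1.23 for Dusp5 (adjusted p = 0.19) and 0.26 for Myc (0.73). On the cholesterol synthesis list 7 of 18 genes rose and none fell, with 8 higher adjusted over the list alone (median 0.46, 0.65 and 0.20 within batches 2 and 3, camera adjusted p = 0.0076, adjusted p = 0.44 with an estimated correlation). Lss, the enzyme that closes the sterol ring system, rose by 1.31 (SE 0.22). The call of the list was lost without a batch term (adjusted p = 0.12), and that of Lss without batch 2 (log2 fold change 1.23, adjusted p = 0.067) and without a batch term (0.87, 0.19). On the antigen presentation list 4 of 14 genes fell and none rose, with 5 lower adjusted over the list alone (median -0.79, -0.54 and -0.76 within batches 2 and 3, camera adjusted p = 0.014, adjusted p = 0.32 with an estimated correlation). This call was lost without batch 3 (adjusted p = 0.068) and without a batch term (0.099), and L2-L batch 1 replicate 3 had a higher batch-adjusted mean of the list than the other L2-L libraries (5.25 against 3.91 to 4.35). On the EMT and invasion list 5 of 16 fell and 3 rose, with 8 lower and 3 higher adjusted over the list alone (median -0.95, -1.02 and -0.41 within batches 2 and 3, camera adjusted p = 0.042, adjusted p = 0.36 with an estimated correlation). Its lower genes included Snai2, a transcription factor also used by squamous basal cells (log2 fold change -8.71, SE 1.26), and the matrix proteins Tnc (-8.20, SE 1.03) and Tgfbi (-9.63, SE 0.89). Without batch 2 all 3 lost their calls, with log2 fold changes of -5.37 for Snai2 (adjusted p = 0.10), -3.18 for Tnc (0.53) and -10.83 for Tgfbi (0.29). This list lost its call without L2-L batch 1 replicate 1, L2-LP batch 2 replicate 2 or L2-LP batch 3 replicate 1 or 2 (adjusted p = 0.064, 0.11, 0.071 and 0.071) and with voom weights (0.078). L2-L batch 3 replicate 1 had a lower batch-adjusted mean of the EMT list than the other L2-L libraries (2.89 against 4.004 to 4.56). It belongs to the shallow batch, where genes with 0 counts can lower such a mean.

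The other 12 lists did not pass camera in L2-LP against L2-L, ERK output among them. Of the fetal and regenerative list 4 genes rose and 8 fell of 18, among them the mesothelin gene Msln (log2 fold change 2.37, SE 0.26) and the surface protein gene Tacstd2 (-3.35, SE 0.29), with an adjusted p of 0.11. The inflammatory list had 6 higher and 4 lower genes of 25 (adjusted p = 0.38), the stem cell and WNT list 4 higher and 1 lower of 21 (0.74), the stress and handling list 3 higher and 3 lower of 14 (0.97), the interferon list 1 higher and 1 lower of 21 (0.18), and the RAS component list 1 higher and 2 lower of 19 (0.57). One of 30 cell cycle genes rose (0.74), 1 of 15 glycolysis genes fell (0.51), 1 of 9 enteroendocrine and tuft cell genes rose (0.42), 2 of 9 fibroblast genes fell (0.22) and 2 of 10 immune and endothelial genes rose (0.88). Adjusted over the list alone, the inflammatory list had 5 lower genes, the stress list 5 higher, the immune and endothelial list 1 lower, the interferon list none lower, and the cell cycle and glycolysis lists none called, and the other counts stayed the same. In all, 1902 genes rose and 1953 fell in L2-LP, of which 1377 and 1181 by at least 2 times, in the edgeR quasi-likelihood test at an adjusted p under 0.05. The count was 372 of 6868 tested genes without batch 2, 1906 of 6322 without batch 1 and 312 of 4980 in batch 3 alone, which is the shallow batch, so that both the libraries and the tested genes were fewer. The L2-LP group had 2 deep libraries, and without the one with more Trp53 counts (batch 2, replicate 1) 2660 genes were called.

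The comparison of L2-LKP with L2-L asked how the genotype with both added letters differed from L2-L. It showed the same picture of epithelial genes as L2-LP. Krt5 on chromosome 15 at 101707070 to 101712898, the main keratin of squamous basal cells, stood at 8609 CPM ± 4392 (n = 5) in L2-L and at 0.107 CPM ± 0.126 (n = 4) in L2-LKP in batches 1 and 2, and at 5399 CPM ± 17.3 (n = 2) and 11.3 CPM ± 5.03 (n = 3), near the floor of 3 counts, in batch 3. Muc5ac on chromosome 7 at 141788972 to 141819231, the secreted mucin of gastric pit cells, rose from 1.86 CPM ± 2.86 to 434 CPM ± 492.6 in batches 1 and 2. Spry4 on chromosome 18 at 38586247 to 38601415, a feedback inhibitor that ERK signalling induces, rose from 1.93 CPM ± 0.963 to 20.05 CPM ± 3.85. Insig1 on chromosome 5 at 28071363 to 28078662, a sterol sensor, rose from 13.5 CPM ± 3.87 to 245 CPM ± 113.

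Of the 15 squamous genes 12 fell and 1 rose, with 12 lower and 3 higher adjusted over the list alone. Krt5 had a log2 fold change of -14.98 (SE 1.40, adjusted p = 1.9e-07), Krt15 of -10.39 (SE 0.50) and Trp63 of -10.50 (SE 0.61). The gene that rose was the cornified envelope gene Sprr1a (1.30), named after its value was seen. The hemidesmosomal collagen Col17a1, outside the list, fell by 12.67 (SE 0.62). The list's median was -7.94, with -8.31, -7.60 and -5.30 within batches 1, 2 and 3 (camera adjusted p = 3.8e-13, adjusted p = 0.00086 with an estimated correlation).

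On the gastric pit list 10 of 11 genes rose and 1, again Psca, fell, with the same counts adjusted over the list alone. Muc5ac rose by 8.37 (SE 1.23) and Vsig1 by 6.48 (SE 0.95). The median was 5.99 with or without the bound for the gene lacking counts in L2-L, and 6.60, 7.47 and 3.16 within batches 1, 2 and 3 (camera adjusted p = 1.8e-06, adjusted p = 0.18 with an estimated correlation). All 6 tested gastric gland genes rose, also adjusted over the list alone (median 4.04, with 4.38, 4.35 and 3.13 within batches, camera adjusted p = 4.3e-05, adjusted p = 0.025 with an estimated correlation), among them the water channel Aqp5 (2.72, SE 0.32) and Pgc, at least 3695-fold higher. On the intestinal list 7 of 14 rose and 2 fell, with the same counts adjusted over the list alone (median 2.26, with 3.95, 3.49 and 0.73 within batches, camera adjusted p = 0.021, adjusted p = 0.36 with an estimated correlation). L2-LKP batch 3 replicate 3 had a lower batch-adjusted mean of this list than the other L2-LKP libraries (0.42 against 2.25 to 3.04), and the list kept its call without it. That library is shallow, so genes with 0 counts can lower such a mean. Agr2, a secretory cell chaperone, rose by 3.79 (SE 0.49).

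ERK pathway output rose in L2-LKP. Of 25 genes 11 rose and 2 fell, with the same counts adjusted over the list alone. Spry4 rose by 3.44 (SE 0.32, adjusted p = 1.9e-07), the ERK phosphatase Dusp5 on chromosome 19 at 53529109 to 53542431 by 2.07 (SE 0.30), Fosl1 by 1.49 (SE 0.31) and Myc by 1.17 (SE 0.23). Dusp6, another phosphatase of ERK, did not pass the test (0.47, SE 0.29, adjusted p = 0.23). The list's median was 0.47, with 0.75, 0.17 and 0.43 within batches 1, 2 and 3 (camera adjusted p = 0.011, adjusted p = 0.18 with an estimated correlation). Without batch 3 the list did not pass camera (adjusted p = 0.082). Fosl1 lost its call without a batch term (log2 fold change 1.64, adjusted p = 0.087).

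The p53 target list fell in L2-LKP, with 17 of 26 genes lower and 1 higher, and 18 lower and 1 higher adjusted over the list alone. Phlda3 fell by 2.97 (SE 0.22, adjusted p = 1.2e-08), Trp53inp1, a stress protein that activates p53, by 1.96 (SE 0.29), Cdkn1a by 1.78 (SE 0.37) and Mdm2 by 0.52 (SE 0.16). The median was -0.77, with -0.83, -0.73 and -0.46 within batches 1, 2 and 3 (camera adjusted p = 3.1e-05, adjusted p = 0.025 with an estimated correlation). The call of Mdm2 (adjusted p = 0.018) was lost without L2-L batch 2 replicate 2, L2-LKP batch 1 replicate 1 or L2-LKP batch 2 replicate 2 (adjusted p = 0.051, 0.057 and 0.056). It was also lost without batch 1 (log2 fold change -0.53, adjusted p = 0.16), without batch 2 (-0.38, 0.27) and without a batch term (-0.60, 0.17). Cdkn1a lost its call without a batch term (-1.20, adjusted p = 0.20). Cdkn2a on chromosome 4 at 89274471 to 89294653 rose by 2.42 (SE 0.30, adjusted p = 4.4e-06), from 74.8 CPM ± 39.7 (n = 5) to 349 CPM ± 78.3 (n = 4) in batches 1 and 2, and Cdkn2b did not pass the test (0.08, SE 0.27).

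Of the 18 cholesterol synthesis genes 15 rose and none fell, also adjusted over the list alone. Insig1 rose by 3.75 (SE 0.47), the sterol demethylase Cyp51 by 1.76 (SE 0.26) and Mvd, an enzyme of the mevalonate pathway, by 1.69 (SE 0.22). The median was 0.93, with 1.10, 1.12 and 0.78 within batches 1, 2 and 3 (camera adjusted p = 1.2e-07, adjusted p = 0.14 with an estimated correlation). On the antigen presentation list 8 of 14 genes fell and none rose, with 9 lower adjusted over the list alone (median -1.60, with -2.20, -0.98 and -0.04 within batches, camera adjusted p = 0.015, adjusted p = 0.32 with an estimated correlation). L2-L batch 1 replicate 3, with a higher batch-adjusted mean of this list than the other L2-L libraries (5.25 against 3.91 to 4.35), is part of this reference too, and the list kept its call without it. The peptide transporter genes Tap1 and Tap2 fell by 2.58 (SE 0.48) and 3.32 (SE 0.43) in the fit, whereas within batch 3 their log2 fold changes were 0.54 and 0.33. On the glycolysis list 2 of 15 rose, with 1 adjusted over the list alone (median 0.33, with 0.63, 0.22 and 0.16 within batches, camera adjusted p = 0.025, adjusted p = 0.79 with an estimated correlation), and on the EMT and invasion list 6 of 16 fell and 2 rose, with 7 and 3 adjusted over the list alone (median -0.90, with -1.71, -0.39 and -0.22 within batches, camera adjusted p = 0.042, adjusted p = 0.36 with an estimated correlation). The calls of both lists were lost without batch 3 (adjusted p = 0.10 and 0.053) and without a batch term (0.11 and 0.055). The glycolysis call was also lost with fry (0.21) and the EMT call with voom weights (0.094). The L2-L reference holds batch 3 replicate 1, whose batch-adjusted mean of the EMT list was below that of the other L2-L libraries (2.89 against 4.004 to 4.56). Genes with 0 counts can lower such a mean in this shallow library. The glycolysis list lost its call without L2-L batch 1 replicate 1 or 2, L2-L batch 3 replicate 2 or L2-LKP batch 1 replicate 1 (adjusted p = 0.084, 0.083, 0.051 and 0.12), and the EMT list without L2-L batch 1 replicate 1, L2-LKP batch 1 replicate 1 or 2 or L2-LKP batch 2 replicate 2 (0.064, 0.062, 0.077 and 0.058).

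The remaining 10 lists did not pass camera in this comparison. The fetal and regenerative list had 4 higher and 5 lower genes of 18 (adjusted p = 0.50), the stem cell and WNT list 5 higher and 6 lower of 21 (0.99), the stress list 6 higher and 4 lower of 14 (0.74), the inflammatory list 2 higher and 7 lower of 25 (0.58), and the RAS component list 5 higher and 3 lower of 19 (0.92). The interferon list had 2 higher and 2 lower of 21 (0.76). One of 30 cell cycle genes rose (0.42) and Mki67, a marker of dividing cells, did not pass the test (log2 fold change 0.31, SE 0.35). Of the fibroblast list 3 of 9 fell (0.11), of the immune and endothelial list 2 rose and 3 fell of 10 (0.98), and 1 of 9 enteroendocrine and tuft cell genes rose (0.74). Adjusted over the list alone, the fetal list had 5 higher and 6 lower genes, the stem cell list 7 lower and the cell cycle list none called, and the other counts stayed the same. In all, 2356 genes rose and 2678 fell in L2-LKP against L2-L, of which 1478 and 1682 by at least 2 times, in the edgeR quasi-likelihood test at an adjusted p under 0.05. The count was 1302 of 6322 tested genes without batch 1, 1402 of 6868 without batch 2, 2503 of 14361 in batch 1 alone, 2757 of 14500 in batch 2 alone and 174 of 4980 in batch 3 alone.

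**Figure D3:**
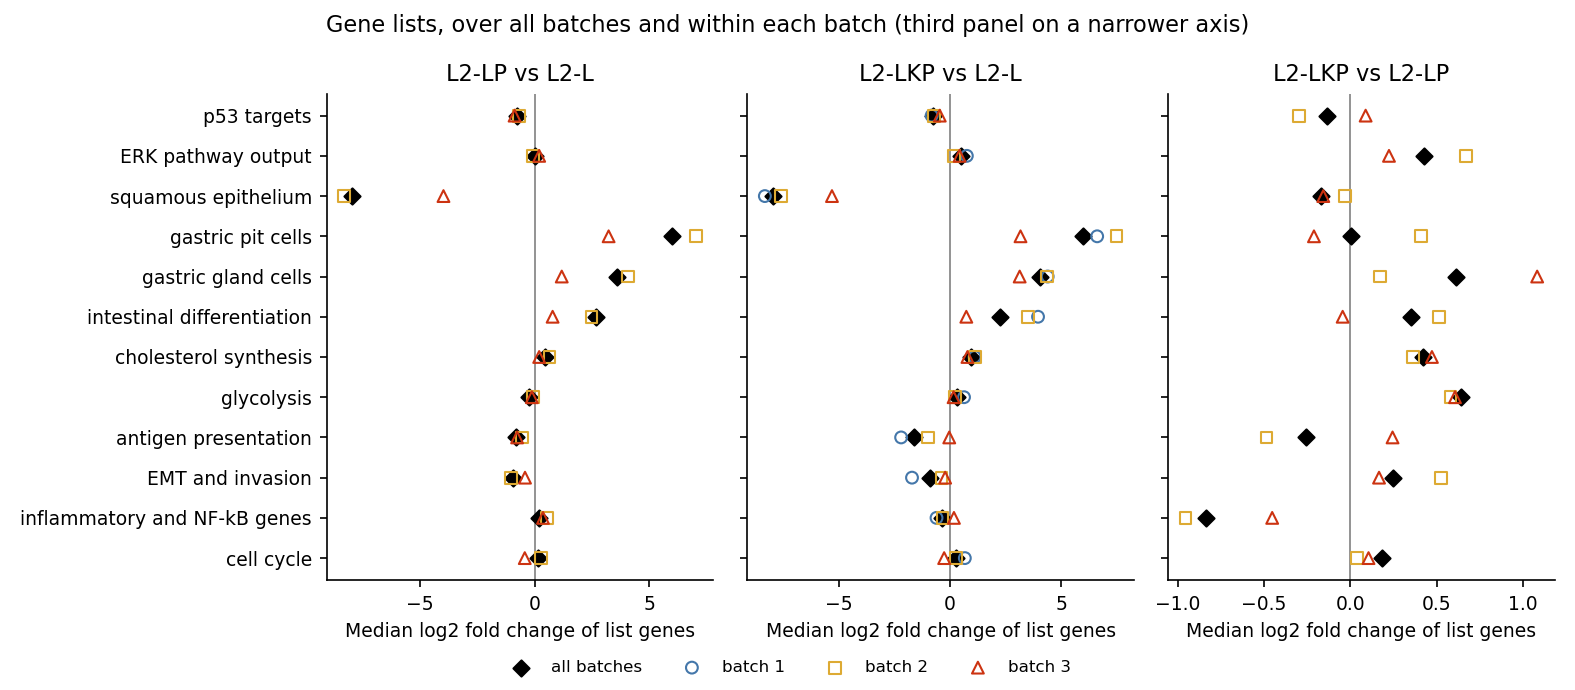
Median log2 fold change of the tested genes of 12 lists in the 3 comparisons, with black diamonds for the fit over all batches and open symbols for the fits within batches 1, 2 and 3. The third panel has a narrower axis. The squamous median is -7.96 in L2-LP and -7.94 in L2-LKP against L2-L and -0.17 between L2-LKP and L2-LP.

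The comparison of L2-LKP with L2-LP, 2 genotypes with low Trp53 counts, asked what the letter K adds. Fewer genes differed. Spry4 stood at 20.05 CPM ± 3.85 (n = 4) in L2-LKP and 5.64 CPM ± 2.13 (n = 2) in L2-LP in batches 1 and 2, a log2 fold change of 2.28 (SE 0.43, adjusted p = 0.0062). The transcription factor gene Etv4 on chromosome 11 at 101769742 to 101785371 rose by 1.77 (SE 0.44) and Ereg by 1.75 (SE 0.51). Ly6a, a surface protein of regenerating epithelium, rose from 698 CPM ± 93.1 to 1762 CPM ± 619 (log2 fold change 1.87, SE 0.29) and Anxa8 fell by 1.83 (SE 0.38). Without batch 3 both lost their calls, with log2 fold changes of 1.56 (adjusted p = 0.051) and -1.78 (0.082), as they did without a batch term (1.71, 0.057 and -1.77, 0.069). Trp53 (-1.999, SE 0.90, adjusted p = 0.17) and Kras (0.11, SE 0.25, adjusted p = 0.83) did not pass the test.

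These 3 ERK genes were the ones called of 25, with 6 higher and 1 lower adjusted over the list alone. The list's median was 0.43, with 0.67 within batch 2 and 0.22 within batch 3 (camera adjusted p = 0.0010, adjusted p = 0.093 with an estimated correlation). Without L2-LP batch 2 replicate 1, Spry4, Etv4 and Ereg lost their calls (adjusted p = 0.060, 0.11 and 0.17), with log2 fold changes of 2.04, 1.75 and 1.92. Ereg also lost its call without L2-LP batch 2 replicate 2 (0.16), L2-LP batch 3 replicate 3 (0.068), L2-LKP batch 1 replicate 2 (0.060), L2-LKP batch 2 replicate 2 or 3 (0.081 and 0.092) or L2-LKP batch 3 replicate 1 or 2 (0.053 and 0.056). Without batch 2 the log2 fold change of Ereg was 0.36 (adjusted p = 0.92). Without batch 3, Etv4 (1.69, adjusted p = 0.11) and Ereg (1.87, 0.051) lost their calls, and without a batch term Spry4 (1.99, 0.28), Etv4 (1.38, 0.58) and Ereg (1.68, 0.50) did. The glycolysis list had no called gene of 15 over all genes and 4 higher adjusted over the list alone (median 0.64, with 0.58 and 0.61 within batches 2 and 3, camera adjusted p = 7.8e-05, adjusted p = 0.41 with an estimated correlation), with log2 fold changes of 0.82 (SE 0.25) for lactate dehydrogenase A, Ldha, and 1.12 (SE 0.35) for the glucose transporter gene Slc2a1. On the cholesterol synthesis list 1 of 18 rose, with 3 adjusted over the list alone (median 0.42, with 0.37 and 0.47 within batches 2 and 3, camera adjusted p = 0.0025, adjusted p = 0.39 with an estimated correlation). On the inflammatory list 3 of 25 fell and 1 rose, also adjusted over the list alone (median -0.83, with -0.96 and -0.45 within batches 2 and 3, camera adjusted p = 0.013, adjusted p = 0.41 with an estimated correlation), among them the macrophage growth factor gene Csf1 (-1.40, SE 0.32), whose call was lost without L2-LP batch 2 replicate 1 and without a batch term (adjusted p = 0.13 in both). The inflammatory list lost its call without batch 3 (adjusted p = 0.10). With fry, the adjusted p was 0.14 for the inflammatory, 0.080 for the glycolysis and 0.068 for the cholesterol list.

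The other 16 lists did not pass camera between L2-LKP and L2-LP. Of the p53 targets 2 of 26 fell and none rose, with 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.73), and Trp53inp1 fell by 2.03 (SE 0.34), a call lost without batch 2 (log2 fold change -2.03, adjusted p = 0.17) and without a batch term (-0.97, 0.82). The squamous list had 1 lower gene of 15 (0.35), the gastric pit list none of 11 (0.80), the gland list 1 higher of 6 (0.34) and the intestinal list 1 lower of 14 (0.82). The fetal and regenerative list had 2 higher and 1 lower of 18 (0.43), the stem cell and WNT list 2 lower of 21 (0.50), the interferon list 2 lower of 21 (0.19), the antigen presentation list 1 lower of 14 (0.82), the EMT and invasion list 1 lower of 16 (0.80), the stress list 1 lower of 14 (0.43), and the immune and endothelial list 1 lower of 10 (0.93). No gene was called among 19 RAS components (0.71), 30 cell cycle genes (0.71), 9 enteroendocrine and tuft cell genes (0.57) or 9 fibroblast genes (0.83). Adjusted over the list alone, the interferon list had 7 lower genes, the stress list 1 higher and the immune and endothelial list 2 lower, and the other counts stayed the same.

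The largest folds between L2-LKP and L2-LP lay outside the lists. The protease inhibitor gene Serpinb2 on chromosome 1 at 107511423 to 107535478 (overlapping Serpinb10) rose by 8.20 on the log2 scale (SE 1.13), from 0.0977 CPM ± 0.0455 to 23.3 CPM ± 34.4 in batches 1 and 2, and the amino acid enzyme gene Bcat1 by 6.61 (SE 1.11). Cym on chromosome 3 at 107211293 to 107221732, which encodes the stomach protease chymosin, fell by 8.89 (SE 1.55), the potassium channel gene Kcnj15 fell by 8.58 (SE 0.98) and the water channel gene Aqp4 fell by 6.93 (SE 0.81). Wnt16 had no count in L2-LKP and was at least 63.0-fold lower. The call of Cym was lost without batch 2 (log2 fold change -7.05, adjusted p = 0.091), and those of Serpinb2 and Wnt16 without a batch term (adjusted p = 0.052 and 0.060). In all, 456 genes rose and 621 fell, of which 207 and 413 by at least 2 times, in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 172 without L2-LP batch 2 replicate 1, 479 and 527 without L2-LKP batch 2 replicates 2 and 3, 703 without L2-LP batch 3 replicate 3, 619 of 6322 tested genes without batch 1, 18 of 6868 without batch 2 and 15 of 4980 in batch 3 alone. In batch 2 alone, where 2 libraries stood against 2, edgeR called 0 genes, with 3980 at an unadjusted p under 0.05, and no other tool was run on that subset.

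The changes of L2-LP and L2-LKP against L2-L were then set side by side. Of the genes called in both, 1317 were higher and 1300 lower in both genotypes and 9 went in opposite directions, so that 67.9% of the genes called in L2-LP were called in L2-LKP with the same sign. Independent lists of these sizes would share 311 higher and 363 lower genes. Both comparisons use the same L2-L libraries, and 20 simulations of unchanged groups against them gave, on average, a correlation of log2 fold changes across genes of 0.394 and a covariance of 0.0966. The observed correlation across genes, which are not independent replicates, was 0.854 and the covariance 3.07, a difference of 2.98 from the simulated covariance. With the L2-L libraries split between the comparisons, 653 and 804 genes were shared in the 2 arrangements, against 96.5 and 128 for independent lists, with correlations of 0.725 and 0.794 and covariances of 2.22 and 2.28. Per direction, the splits shared 238 and 375 higher genes, against 33.6 and 60.8 for independent lists, and 415 and 429 lower genes, against 63.0 and 66.9.

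The single L2-LK library, in batch 3, has no replicate, and its values describe that library. Like L2-LP and L2-LKP it held little of the basal keratin Krt5, with 26.5 CPM (exact Poisson interval 11.4 to 52.2) against 4961 CPM in the L2-L mean of batch 3. Other genes of the squamous list, named after their values were seen, were not lower: Sprr1a stood at 955 CPM against 471 CPM in L2-L, Krt4 at 474 against 366 CPM and Ivl at 146 against 27.6 CPM. Cdkn2a in the L2-LK library, whose Trp53 level lay in the range of L2-L, stood at 298 CPM (interval 240 to 367) against 65.1 CPM in L2-L (n = 2). L2-LP held 313 CPM ± 20.5 (n = 3) and L2-LKP 521 CPM ± 125 (n = 3) of it. Unlike L2-LP and L2-LKP, the L2-LK library stood above L2-L in p53 targets. Cdkn1a, on chromosome 17 at 29090976 to 29100727, was at 1422 CPM (interval 1291 to 1563) against 353 CPM in L2-L (n = 2), 168 CPM ± 20.6 (n = 3) in L2-LP and 224 CPM ± 122 (n = 3) in L2-LKP. Mdm2, on chromosome 10 at 117688875 to 117710758, was at 166 CPM (interval 123 to 218) against 29.1, 30.1 ± 8.46 and 33.4 ± 2.45 CPM, and Psrc1, on chromosome 3 at 108383839 to 108388231, at 192 CPM (interval 146 to 249) against 24.8 CPM in L2-L and 13.9 ± 1.78 CPM in L2-LKP, with a mean below the floor of 3 counts in L2-LP.

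The median log2 difference of 22 p53 targets from the L2-L mean of batch 3 was 0.85 in L2-LK, above all 10000 random lists (percentile 100), and lay between -0.80 and -0.74 in the 3 L2-LP libraries and between -0.62 and -0.34 in the 3 L2-LKP libraries. The reference holds 2 libraries, of which replicate 1 had a lower batch-adjusted mean of this list than all other L2-L libraries (4.97 against 5.68 to 5.8004). Genes with 0 counts at this depth can lower such a mean. The median of L2-LK was 0.80 without that library and 0.88 without replicate 2. Not all members were higher: Phlda3 stood at 418 CPM against 514 CPM in L2-L, and Perp at 345 against 578 CPM. The median of 20 ERK output genes was 0.68 (percentile 100), against 0.09 to 0.24 in L2-LP (percentiles 74.9 to 94.3) and 0.24 to 0.46 in L2-LKP (percentiles 92.4 to 99.6). Ccnd1, cyclin D1, was at 1747 CPM (interval 1601 to 1902) against 596 CPM in L2-L, 1074 CPM ± 178 in L2-LP and 833 CPM ± 172 in L2-LKP. Not all members were clearly higher: Egr1, named after its value was seen, had 1 count, or 3.31 CPM (interval 0.0839 to 18.5), against 19.8 CPM in L2-L, Dusp4, named likewise, stood at 16.6 CPM (interval 5.38 to 38.7) against 19.8 CPM, Spred1 at 26.5 against 31.0 CPM and Dusp6 at 56.3 CPM (interval 32.8 to 90.2), close to 52.4 CPM. The squamous median was -2.79, next to -2.86 to -2.83 in L2-LP and -3.22 to -2.84 in L2-LKP, and the gastric pit median was 2.26, within the range of L2-LP (1.07 to 3.93) and of L2-LKP (0.26 to 3.55). The lowest pit median, 0.26, was that of L2-LKP replicate 1. Over 8070 genes, the Spearman correlation of L2-LK across genes was 0.832 to 0.850 with the L2-LKP libraries, 0.778 to 0.825 with L2-LP and 0.780 to 0.804 with L2-L.

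**Figure D4:**
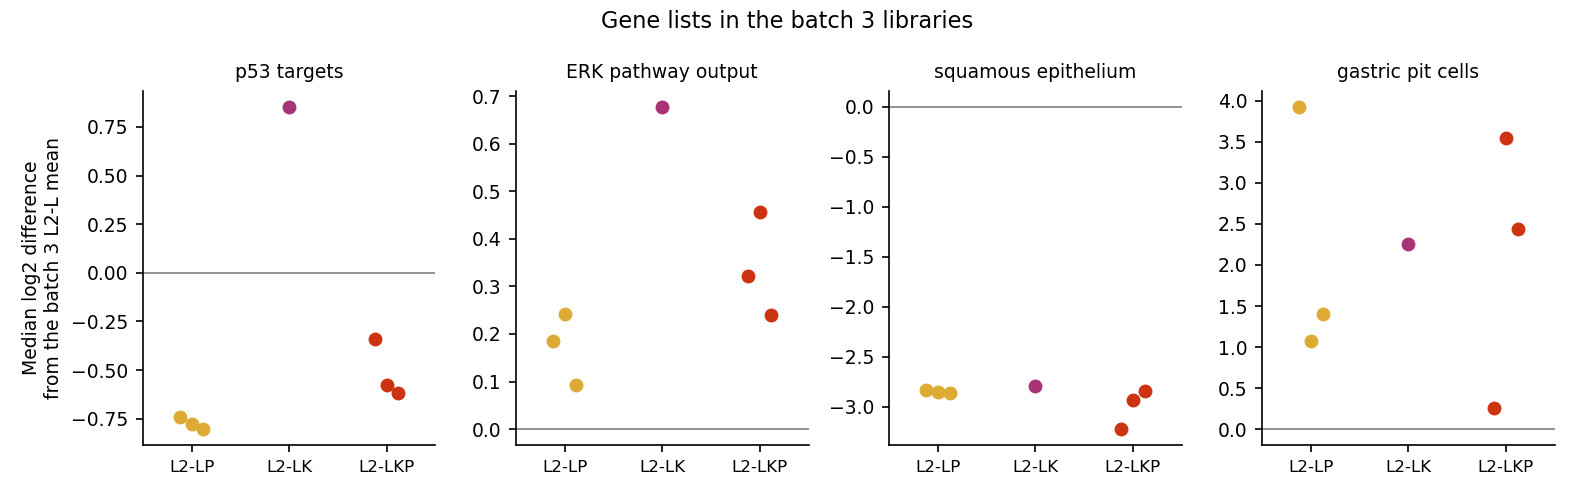
Median log2 difference of 4 gene lists from the mean of the 2 L2-L libraries of batch 3, with 1 point per L2-LP, L2-LK and L2-LKP library of that batch. The L2-LK point lies at 0.85 for p53 targets, above all 6 others.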

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

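The test for samples that stand apart was fixed before the result was seen. It was run on the batch-adjusted log2 CPM of Trp53 and Kras and the mean of each gene list in each group of 5 or 7 libraries, and a library was listed when its gap to the nearest other library took up an unusually large share of the range of its group by Dixon's test. Of 66 groups 7 were listed, and chance lists about 1 in 20 groups, or 3.3 here. No explanation was tested for any of them.

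In L2-L, replicate 1 of batch 3 stood below the other libraries on 3 lists. Its mean p53 target level was 4.97, against 5.68 to 5.8004 in the others (share of the range 0.853). Its mean level of RAS pathway components was 5.69, against 6.13 to 6.26 (0.769), and that of the EMT and invasion list was 2.89, against 4.004 to 4.56 (0.667). Replicate 3 of batch 1 in L2-L had a lower level of the fetal and regenerative list, 8.51 against 9.08 to 9.47 (0.598), and a higher level of antigen presentation genes, 5.25 against 3.91 to 4.35 (0.670).

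In L2-LKP, replicate 3 of batch 3 had a mean level of intestinal genes of 0.42, against 2.25 to 3.04 in the other libraries (0.699). In L2-LP, replicate 1 of batch 2, which is also the deep library with more Trp53 counts, had a mean level of stress and handling genes of 5.36, against 6.01 to 6.27 (0.715).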

How the results depend on the processing

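Alternatives chosen after seeing the data were the list tests without batch 3 or with voom weights, the overlap and the list members without single batches or L2-LP batch 2 replicate 1, and other references for L2-LK, including each L2-L library of batch 3 left out. In the order L2-LP against L2-L, L2-LKP against L2-L and L2-LKP against L2-LP, 3855, 5034 and 1077 genes were called. The counts stayed within 1.5 times of these under RLE normalization, both other low-count filters, all 20 libraries and the omission of batch 3. Similar counts need not be the same genes. Without batch 3, 3956, 5876 and 985 genes were called, of which 2962, 4501 and 505 were among the 3855, 5034 and 1077. The counts were 1568, 2485 and 29 without a batch term. They were 6981, 8549 and 4818 with a random effect for genotype and number in limma-voom, whose estimated correlation was -0.093. They were 2558, 3160 and 620 with a 2-fold threshold, which by construction only removes genes. They were 1906, 1302 and 619 of 6322 tested genes without batch 1, 372, 1402 and 18 of 6868 without batch 2, and 312, 174 and 15 of 4980 in batch 3 alone, where fewer libraries and fewer tested genes were not separated. L2-LKP against L2-L gave 2503 in batch 1 alone and 2757 in batch 2 alone, and L2-LKP against L2-LP gave 0 by edgeR in batch 2 alone, with 3980 at an unadjusted p under 0.05. With only the 2 groups compared in the fit, 2530 genes were called for L2-LP against L2-L and 633 for L2-LKP against L2-LP, for which the Wald test of DESeq2 called 2408. Where the number of libraries did not change, the cause was not tested.

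Leaving out 1 library at a time gave 2660 to 3964, 4115 to 5159 and 172 to 1379 genes, and 19 to 23 called list tests, against 22 with all libraries. The lowest counts of 2660 and 172 came without L2-LP batch 2 replicate 1. For L2-LKP against L2-LP, 479, 527 and 703 genes were called without L2-LKP batch 2 replicate 2, L2-LKP batch 2 replicate 3 and L2-LP batch 3 replicate 3. With an estimated correlation 5 list tests were called, and fry called 22, of which 18 were also called by camera. The calls that fry added were lower fetal and regenerative and fibroblast lists in both comparisons with L2-L. Its adjusted p was 0.0013 and 0.015 for these lists in L2-LP and 0.0017 and 0.0039 in L2-LKP. Over 1060 values of list tests under alternatives, 1006 kept their direction and call, 44 lost a call, 10 gained one and 0 reversed. Over 4231 values of named genes, 3780 kept both, 364 lost a call, 82 gained one and 5 reversed.

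The reversed log2 fold changes were 0.048 for Rps27l in L2-LP without a batch term, -0.79 for Insig1 and -0.060 for Myc in L2-LP in batch 3 alone, -0.029 for Aurka in L2-LKP against L2-L in batch 3 alone, and -0.11 for Ly6d between L2-LKP and L2-LP in batch 2 alone. The cause was not tested.

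With the replicate number as a block within batch, 204 genes were called between L2-LKP and L2-LP. Over 13 pairs of libraries with the same number, correlations lay between -0.08 and 0.26. The highest was for replicate 2 of L2-LP and L2-LKP in batch 2. These values gave no clear sign that the numbers pair the samples. They cannot exclude it, since the groups are small and many pairs come from the shallow batch. The count of 204 is therefore not set aside. Replicate numbers also recur within a genotype across batches, and no label says whether they name one culture line. Of 6 deep libraries whose number recurs, 1 correlated best with its own number in the other deep batch. This check is too small to exclude that libraries with one number share a line.

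The overlap of L2-LP and L2-LKP changes was 2617 genes, and 653 and 804 with the L2-L libraries split between the comparisons, where each comparison has fewer libraries. It was 2718 without batch 3 and 2126 without L2-LP batch 2 replicate 1. The squamous median of L2-LK was -2.79, and -3.57 with a prior count of 0.5. Against the mean of the batch 3 L2-LKP or L2-LP libraries it was 0.35 or 0.23, the p53 target median was 1.24 or 1.31 and the ERK output median was 0.44 or 0.49. Those settings ask another question, since they compare L2-LK with other genotypes than L2-L. With either L2-L library of batch 3 left out of the reference, the squamous median was -3.44 to -2.02, the p53 target median 0.80 to 0.88 and the ERK output median 0.57 to 0.84.

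Depth limits batch 3, where 3 counts stand for 9.94 to 13.3 CPM, so that lower levels were not detectable there in single libraries.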

Other observations

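All tests of explanations in this part were chosen after the result was seen, except the test of p53 targets against columnar identity and the regroupings of libraries.

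Some lists that did not pass camera in the comparisons named here held genes that moved far apart. On the fetal and regenerative list, Msln rose by 2.12 (SE 0.22) in L2-LKP against L2-L and Tacstd2 fell by 3.61 (SE 0.25), in the quasi-likelihood test of edgeR. By fry, this list was lower on balance in L2-LP (adjusted p = 0.0013) and in L2-LKP (0.0017) against L2-L. On the stem cell and WNT list, Prom1 rose by 2.88 (SE 0.29) in L2-LP and by 1.78 (SE 0.25) in L2-LKP. On the inflammatory list, the antimicrobial lectin gene Reg3g rose by 5.95 (SE 0.72) in L2-LKP and the adhesion gene Icam1 fell by 1.80 (SE 0.21). On the stress and handling list the heat shock gene Hspa1b fell by 2.35 (SE 0.34) in L2-LP and by 1.74 (SE 0.27) in L2-LKP, and Jun was lower in L2-LKP than in L2-LP by 1.68 (log2 fold change -1.68, SE 0.33), a call lost without L2-LP batch 2 replicate 1 (-1.44, adjusted p = 0.063), without batch 2 (-1.97, 0.077), without batch 3 (-1.60, 0.060) and without a batch term (-1.36, 0.28).

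Other groupings of the same libraries within batches were fitted in the same way. For L2-LP against L2-L 1 of 60 splits, the real one, gave as many as 3855 genes, and the highest of the others gave 2360. For L2-LKP against L2-L it was 1 of 100 drawn from 600, with 5034 genes against 3955, and for L2-LKP against L2-LP 1 of 60, with 1077 against 783. Chance assignment of the libraries is argued against for the 3 counts but not excluded, since 60 splits can give no share below 0.0167. In the comparisons with L2-LP the libraries of batch 1 could not be regrouped.

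The squamous list was lower in L2-LP and L2-LKP than in L2-L, in 12 of its 15 genes. An exchanged library is argued against by the summed level of the list, whose lowest L2-L library (10018 CPM) was 2.90 times the highest L2-LP or L2-LKP library (3458 CPM). A difference between batches is argued against by the within-batch medians, the smallest of which was -3.96. Whether loss of Trp53 or the origin of the cultures may explain the pattern cannot be told apart: the L2-LK library, with Trp53 counts in the range of L2-L, had a median of -2.79, but it is 1 library and no label gives the origin of a culture. A biological difference between genotypes stays open.

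Batch 3 held transcripts that batches 1 and 2 nearly lacked in the same genotypes. Reads or RNA from other libraries of the pool are a candidate explanation that the values here cannot decide. Columnar genes in L2-L stood at a median of 6.96% of their L2-LKP level in batch 3 (2.37% to 59.4%) and 0.0428% in batch 2, higher for 11 of 11 genes. Percents of genes near the floor rest on few counts. Cdx2, at 22.7% in batch 3, had a mean of 3.72 CPM in L2-L (scaled by the total count), below the floor of 3 counts. Squamous genes in L2-LP and L2-LKP stood at 1.10% of L2-L (0% to 3.31%) against 0.126%, higher for 6 of 7. Only genes with a very low percent in batch 2 were included, so the choice of genes favoured a higher percent in batch 3. Fibroblasts stay open: Vim stood at 322 to 650 CPM in batch 3 and 0.481 to 56.6 CPM before, and the summed CPM of Col1a1, Col1a2 and Col3a1 was 13.3 or more in batch 3 and 2.47 or less before. That sum reached at most 0.128 times Vim, but the ratio in fibroblasts is not in the tables. Another library or counting method stays open, since Trp53 in L2-LKP stood at 40.7% of L2-L in batch 3 and 1.55% in batches 1 and 2, and gene totals hold no positions. No biological explanation was tested.

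The p53 target list was lower in L2-LP and L2-LKP than in L2-L. Perp, Phlda3 and Dcxr, picked as genes that epidermis also uses, did not account for the whole shift. Without them 8 and 14 of 23 members were lower, 2.56 and 3.27 times the share among all genes. Whether squamous cells also use other members was not tested, so these values cannot decide on genes of epidermis as a cause. A difference between squamous and columnar cultures may contribute and stays open: the L2-LK library, which had little Krt5 and Krt15, had a median of 0.85. The bound written before the test would exclude this explanation at that value, but it was too loose, because L2-LK is 1 library and stands above L2-L itself, so that it gives no baseline for columnar cells. Loss of Trp53 activity, the biological explanation the design names, stays open.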
